A study of Mus musculus with 4 samples.

How the data were processed

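RNA immunoprecipitation followed by sequencing was used to recover RNA bound to Flag-tagged Lin28b from mouse cells labelled as pancreatic cancer-associated fibroblasts (CAFs). Per the labels' protocols, lysates were prepared with a commercial RIP kit, precleared on protein A/G beads and incubated with bead-coupled anti-Flag antibody, and libraries of recovered and input RNA were made with a stranded mRNA kit. There were 4 libraries in 4 groups of 1: the wild-type IP, the wild-type input, the mutant IP and the mutant input. The mutant is described in the labels as deficient in RNA binding. No group had a replicate, so no difference below has a replicate check, and every value describes single libraries.

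Per the submitters' processing notes, the tools were HISAT2 2.1.0, MACS2 2.2.7.1, HOMER 4.11.1 and bedtools, and the genome builds named were mm10 and GRCm38, with no role given for each. The authors' 2 deposited gene tables gave, for each construct, 1 level per gene in the IP and 1 in the input. The file headers name no unit for these deposited levels, and they were read as FPKM from the values. In 443 single-exon pseudogenes of the mutant table, the evidence behind the authors' p-value scaled with gene length (Spearman rho across genes 0.970), so the levels are per kilobase, and column sums between 207301 and 321238 speak against TPM. Read totals are not given, so the depth of every library is unknown and no counting interval was computed for any level. The lowest value of a gene's higher library was 0.100 in each table.

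Per the file headers, the authors also gave a log2 ratio of IP over input, a p-value and a q-value for each gene. The deposited log2 ratio equals log2 of (IP level + 0.01) over (input level + 0.01) to within 1.57e-09, and the log2 ratios and folds in the text were computed from the levels in this way. The authors' deposited q-value compares 2 libraries and not 2 conditions, and the test behind it is not given in the sources used here. Gene symbols stood in the mutant table alone and were carried to the wild-type table by gene identifier: 13478 of its 14755 genes obtained a symbol and 1277 did not. The levels of the 2 tables were normalised separately by the authors, so levels set side by side across constructs carry that limit.

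The deposited peak lists follow the narrowPeak layout, with 1 list per IP and each strand called apart, and with no pooling since there was 1 library per list. In that layout the authors' score is a display value, the fold is the enrichment at the summit, the −log10 columns hold the p-value and q-value, and the last column holds the distance of the summit from the peak start. Whether the input served as the control of the peak calling is not given in the sources used here. Score and −log10 p-value were not used beyond ranking and filtering within a list, and each fold of a peak is the authors' own value.

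A gene was called enriched where its IP level was at least 2-fold above input, and lower where it was at least 2-fold below, each with an authors' q-value under 0.05. A gene was called wild-type-specific where it was enriched in the wild-type IP and its log2 ratio exceeded that in the mutant IP by at least 1, and mutant-specific for the converse. Peaks were called shared where they overlapped a peak of the other list on the same strand by at least 1 base. Each peak was given to the gene, from the 2 tables, whose span held the summit on the same strand, with named genes before predicted ones and then the shortest span first. Peaks outside such genes were compared with the opposite strand and with RefSeq gene spans of the same build. Exons and untranslated regions were not assigned and Lin28 sequence motifs were not analysed here, since no exon models or genome sequence were used. Exact Clopper-Pearson 95% intervals were given for shares of peaks and cover counting error alone.

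In total 30 gene lists were fixed before the data were examined. For the 25 lists with at least 5 measured members, the list's median was placed among the medians of 10000 random lists of the same size, drawn to match the list over 10 classes of mean input level. The percentile describes these libraries and is not a p-value. Across 25 lists, chance alone would put 1.25 outside the central 95%. Named genes followed a rule that was also fixed before the data were examined: Lin28b; the 10 highest and 5 lowest past the threshold in each table and in the difference; the genes of the 10 strongest shared and wild-type-alone peaks; up to 4 members per list with the highest absolute ratio past the threshold; and Actb, Gapdh and Malat1. Predicted genes, pseudogenes and genes below a level of 1 in the higher library were left out of the ranked parts. The genes of mutant-alone peaks and other genes named outside this rule were chosen after their values were seen. A list of 50 interferon-stimulated genes was written after the inputs had been compared.

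The alternatives tried were other overlap rules, stricter peak filters, a mutant list shortened to the length of the wild-type list, a fold of at least 4, pseudocounts of 0.1, 1 and 5, genes in the upper 50% by level, centring on the median of all genes, and unmatched random lists. Alternatives chosen after seeing the data were lists matched on level and gene span, centring within classes of gene span, and restrictions to genes with similar inputs, to protein-coding genes and to genes with no 0. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on levels simulated for 13478 genes, of which 200 were raised 4-fold in the wild-type IP. For the difference between the constructs, 100% of the changed genes were recovered with 0 false calls. Of 500 planted shared peaks, 500 were found. The simulated libraries otherwise shared the same gene levels with little noise, and the planted peaks were shifted copies. Input differences, the trend with gene span and the q-value filter were not simulated, so the computation alone was checked.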

Results

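The data were gene levels and peak lists from RNA immunoprecipitation with an anti-Flag antibody in mouse cells labelled as pancreatic CAFs, the stromal fibroblasts of pancreatic tumours. The cells overexpressed Flag-tagged Lin28b, an RNA-binding protein known for blocking maturation of the let-7 microRNAs and for binding many mRNAs, either as the wild type or as a mutant deficient in RNA binding. The question was which RNAs the wild-type protein recovered, with the mutant as the control. There were 14755 genes in the wild-type table, 14427 genes in the mutant table and 13478 genes in both; the depth of the libraries is unknown. The wild-type peak list held 11912 peaks and the mutant list 15931. There was 1 library in each of the 4 groups, so differences had no replicate check and no test between constructs was possible.

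Lin28b itself was present in all libraries, at 13.8 FPKM in the wild-type input and 30.01 in the mutant input. Its own RNA (10:45376620-45486395, GRCm38) stood at 8.99 in the wild-type IP and 36.7 in the mutant IP, a log2 ratio of IP over input of −0.62 for the wild type and 0.29 for the mutant, both short of the 2-fold threshold. The abundant mRNAs Actb and Gapdh, which encode cytoskeletal actin and a glycolytic enzyme, had less RNA in the IP than in the input, short of the threshold for Gapdh in the wild type. For Actb the log2 ratio was −1.02 in the wild type and −1.64 in the mutant, and for Gapdh it was −0.98 and −1.60. The nuclear noncoding RNA Malat1 had a log2 ratio of −0.10 in the wild type and −2.07 in the mutant.

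The inputs showed which genes these cells expressed. The epithelial keratins Krt8, Krt18 and Krt19 stood at 601, 395 and 665 FPKM in the wild-type input and at 494, 441 and 322 in the mutant input, and the epithelial cadherin Cdh1 at 219 and 114. Of the fibroblast genes, Vim stood at 607 and 547, Fn1 at 118 and 74.6 and Sparc at 93.8 and 83.8, whereas the fibrillar collagen gene Col1a1 stood at 0.722 and 0.404, the smooth muscle actin gene Acta2 at 0.227 and 0.524, and the receptor gene Pdgfra at 1.33 and 0.860. Of 24 epithelial markers, 15 were listed in both tables, and of 20 pan-fibroblast markers, 6 were. Of the markers of other cell types, 4 of 25 macrophage and leukocyte, 3 of 18 endothelial, 3 of 14 pericyte and smooth muscle and 0 of 25 acinar genes were listed in both.

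**Figure D1:**
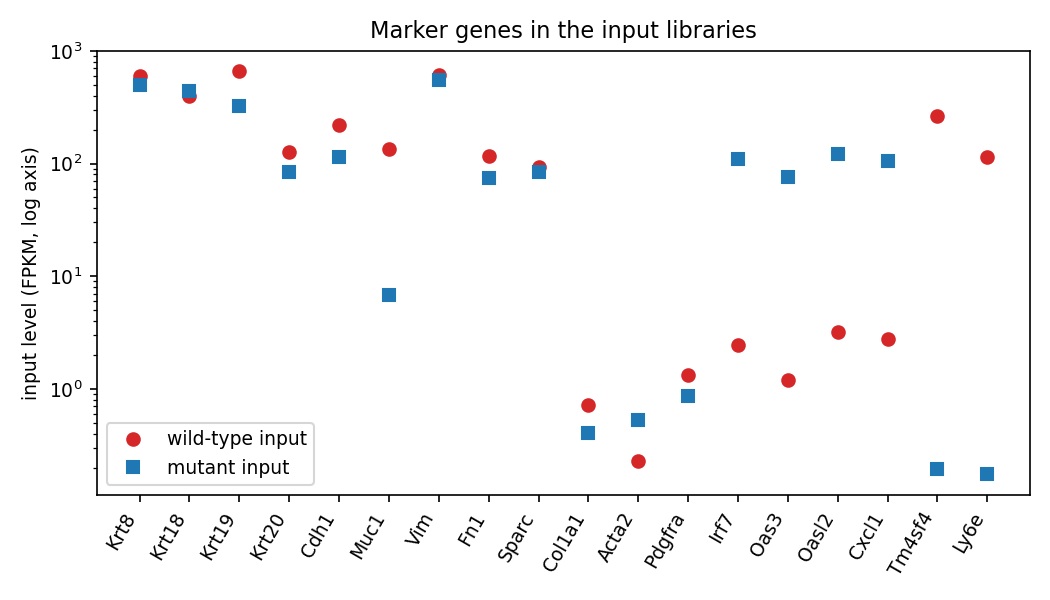
Level of marker genes (FPKM, log axis) in the wild-type input (circles) and the mutant input (squares), 1 library each. Krt8 stands at 601 and 494 and Vim at 607 and 547, Col1a1 lies below 1 in both inputs, and Irf7, Oas3, Oasl2 and Cxcl1 are higher in the mutant input while Tm4sf4 and Ly6e are higher in the wild-type input.

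The 2 inputs differed in other genes. Their levels correlated at 0.938 across genes (Pearson, log2 of level + 1; genes are not independent replicates), and 543 genes were at least 2-fold higher in the wild-type input and 496 in the mutant input on that scale. The membrane protein gene Tm4sf4 stood at 263 in the wild-type input and 0.194 in the mutant input, Ly6e at 114 and 0.174, and the mucin gene Muc1 at 134 and 6.77. The interferon-response genes Irf7, Oas3 and Oasl2 stood at 109, 76.2 and 121 in the mutant input and at 2.45, 1.21 and 3.19 in the wild-type input. The levels of the 2 tables were normalised separately. These differences between the inputs accompany every comparison of the constructs.

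In the wild-type IP, the strongest recovery among well-measured named genes was that of Vbp1, Rpl22l1 and Hmga2. Vbp1, which encodes a prefoldin subunit, stood at 155 FPKM in the IP and 14.5 in the input, a 10.7-fold enrichment. Rpl22l1, a paralogue of a ribosomal protein gene, was enriched 10.2-fold, from 65.7 to 673. Hmga2 (10:120361275-120476469), which encodes a chromatin architectural protein and is a textbook let-7 target, was enriched 9.39-fold, from 39.5 to 371. The zinc finger gene Rsl1 was enriched 8.05-fold, the mitochondrial carrier gene Slc25a40 6.79-fold, Naf1, whose product assembles H/ACA ribonucleoproteins, 6.49-fold, and the ubiquitin-conjugating enzyme gene Ube2d3 5.61-fold. Spata22 and Ramp2 were listed at 0 in the wild-type input and stood at 1.50 and 1.21 in the IP. The histone gene H2ac18 rose from 0.00175 to 6.48, but its input level lies below the pseudocount and it has near-identical copies that can share reads, so its value is uncertain. At the other end were the telomerase RNA Terc, at 0.0911 in the IP and 21.0 in the input, Pet117, at 0.0508 and 1.44, and Rps27rt, at 0.398 and 6.17, while Spink4 and Apoa1 were listed at 0 in the IP.

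Across the wild-type table, 1092 genes were enriched and 3169 were lower at the thresholds set, and the median log2 ratio over all genes was −0.29. After centring on that median the split became 1804 enriched and 2175 lower genes. With a pseudocount of 1 the split was 509 and 1501. The 1277 genes listed in the wild-type table alone had no symbol, and 145 of them were enriched.

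In the mutant IP, Atm and Prkdc, kinases of the DNA damage response, were enriched 5.84-fold and 5.28-fold, and Pdik1l, a kinase gene, 7.89-fold. The scaffold gene Ahnak rose from 292 to 1420 FPKM (4.86-fold), the transferrin receptor gene Tfrc from 62.4 to 301 (4.82-fold) and the nesprin gene Syne2 from 28.6 to 138 (4.81-fold). Ptpn4, Vps13a and Zfp82 were enriched 5.14-fold, 4.93-fold and 5.73-fold. In the wild-type IP, Atm, Prkdc, Ptpn4, Vps13a, Zfp82, Tfrc and Pdik1l were enriched as well, by 2.18-fold to 3.05-fold. Cox7a1, Ly96, Npb, Gstp2 and Terc were listed at 0 in the mutant IP and stood at 5.10, 3.60, 3.36, 2.56 and 12.5 in its input.

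Across the mutant table, 863 genes were enriched and 5196 were lower, with a median log2 ratio of −0.61. After centring, 2298 were enriched and 3294 lower, and with a pseudocount of 1 the split was 440 and 3082. Among genes in both tables, 947 were enriched in the wild type, 738 in the mutant and 226 in both, where 51.9 would be shared by independent lists. For lower genes the counts were 2754, 4819 and 1958, with 985 for independent lists. The log2 ratios of the constructs correlated across genes with Pearson's r of 0.408 and Spearman's rho of 0.514.

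**Figure D2:**
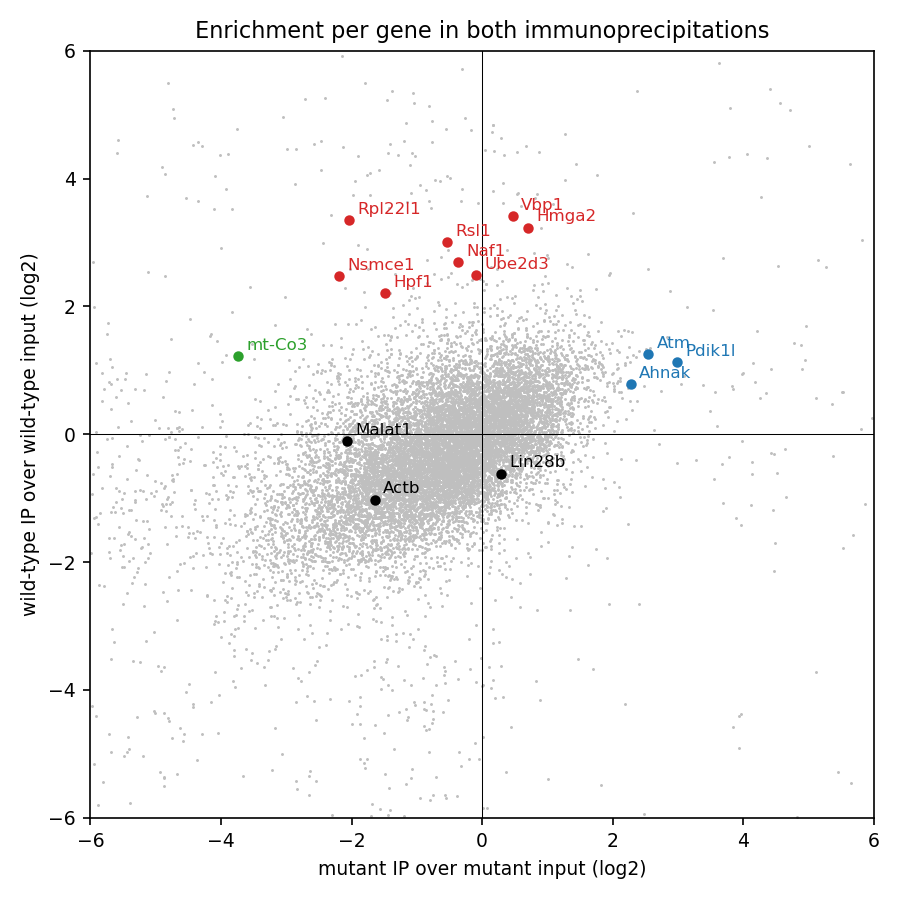
Log2 ratio of IP over input per gene in the mutant (horizontal axis) and the wild type (vertical axis), for genes in both tables, with 1 library on each side of each ratio and 194 genes beyond the axis limit of 6 left out. Vbp1, Rpl22l1 and Hmga2 stand above 3 in the wild type, and Atm, Ahnak and Pdik1l stand above 2 in the mutant.

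The difference between the constructs was led by genes that were enriched with the wild-type protein and lower with the mutant. Rpl22l1 had a log2 ratio of 3.36 in the wild type and −2.04 in the mutant. Nsmce1, encoding a subunit of the SMC5/6 complex, had 2.47 and −2.19, Smim19 had 2.29 and −2.09, the RNase P subunit gene Rpp38 had 1.39 and −2.44, Mterf1a, a mitochondrial transcription termination factor gene, had 1.57 and −2.62, and the spliceosomal Sm protein gene Snrpe had 1.17 and −2.95. The mitochondrially encoded mt-Co3 stood at 65.6 against 28.2 in the wild-type input and at 1.99 against 26.6 in the mutant input. Hmga2 and Vbp1 exceeded the mutant ratio by 2.53 and 2.95 on the log2 scale. At the other end, Plin4, Zfp873, Myh14 and Tnxb were enriched in the mutant, and their log2 ratio in the wild type lay −2.09, −2.05, −2.02 and −1.97 from that in the mutant. In the mutant IP they stood at only 2.16, 4.53, 1.09 and 1.90 FPKM, against 0.896, 1.39, 0.287 and 0.876 in its input. At such levels the fold depends on the pseudocount. Tnxb stood at 13.5 in the wild-type input. Rnf125 was listed at 0 in the wild-type IP and stood at 3.35 in the mutant IP.

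In total 528 genes were wild-type-specific and 272 mutant-specific, and the difference was not tested. After centring each comparison on its median the balance turned, to 583 and 754. Over all 13478 genes the wild-type ratio exceeded the mutant ratio by a median of 0.32. Of the wild-type-specific genes, 310 had inputs within 2-fold of each other and 200 had a mutant input at least 2-fold above the wild-type input, both with a pseudocount of 0.01. With a pseudocount of 1, 242 of the 528 remained.

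The difference followed the span of the gene. Among 1126 protein-coding genes with spans up to 4.65 kb, the median log2 ratio was −0.99 in the wild type and −1.84 in the mutant. Among 1126 genes with spans above 111 kb it was 0.06 and 0.25. The median span was 16.8 kb for wild-type-specific genes, 31.6 kb for mutant-specific genes and 18.4 kb for all genes in both tables.

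**Figure D3:**
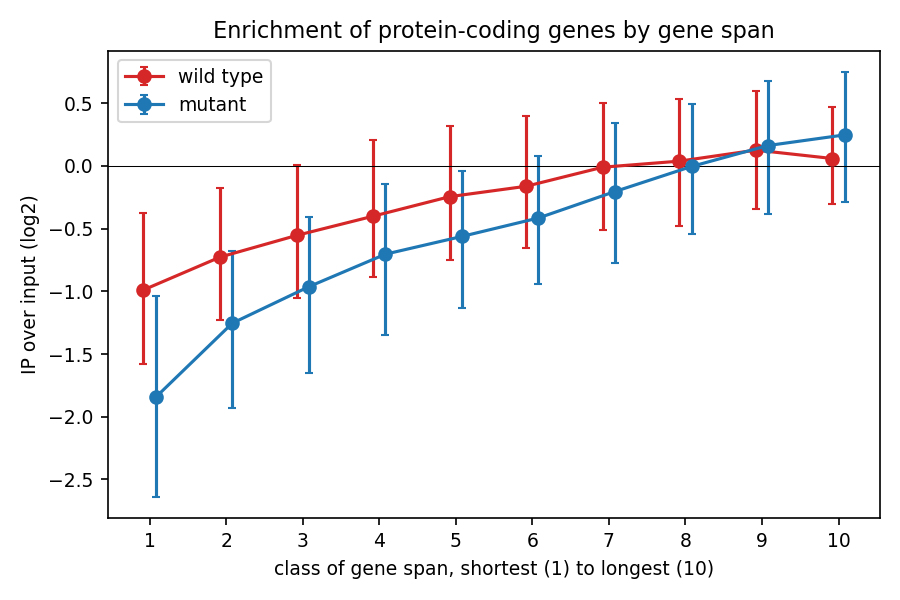
Median log2 ratio of IP over input of protein-coding genes in 10 classes of gene span, each of 1126 genes, in the wild type (red) and the mutant (blue), with bars from the lower to the upper quartile across genes. The median rises from −0.99 to 0.06 in the wild type and from −1.84 to 0.25 in the mutant.

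Mitochondrially encoded transcripts, long noncoding RNAs, ribosomal protein mRNAs and nuclear-encoded oxidative phosphorylation mRNAs had the largest median differences among the 25 lists with a percentile. All 13 measured mitochondrially encoded genes had a higher ratio in the wild type than in the mutant, with list medians of 0.66 and −2.04. Of these genes, 2 were enriched in the wild type and 13 were lower in the mutant. Their mutant median lay at percentile 0.695 of random lists matched on level, but at 98.6 once gene span was matched too. Of 85 cytosolic ribosomal protein genes, 3 were enriched and 37 lower in the wild type, against 1 and 79 in the mutant, with medians of −0.94 and −2.67. Rplp1 was 3.03-fold lower in the wild-type IP and 12.2-fold lower in the mutant IP, while Rps16 was enriched 3.30-fold in the wild type, with part of its reads open to sharing with pseudogene copies. Of 86 nuclear genes of oxidative phosphorylation, 37 were lower in the wild type and 76 in the mutant, with medians of −0.88 and −2.65. Ndufa3, Ndufb2 and Atp5e had log2 ratios of −1.77, −1.87 and −0.13 in the wild type and −4.02, −4.14 and −4.55 in the mutant. Of 18 measured genes on a list fixed as nuclear long noncoding RNAs, 5 were lower in the wild type and 16 in the mutant. Gas5, on that list, had log2 ratios of −0.89 and −3.03. The location of these RNAs in the cell was not measured, so the list name is not a result. The difference between the constructs of each of these 4 lists lay at percentile 100 of random lists matched on level. For 67 replication-dependent histone genes, with medians of −1.87 and −2.83, it lay at percentile 99.7, but at percentile 3.07 once lists were also matched on gene span.

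Of 30 mRNAs reported as LIN28 targets, 20 carried a peak in the wild type and 13 in the mutant. Their median log2 ratio was 0.22 in the wild type (percentile 99.8) and −0.10 in the mutant (percentile 99.7), which became 0.49 after centring, and the difference lay at percentile 42.6. Of 26 let-7 target mRNAs, 3 were enriched in the wild type and 2 in the mutant, with medians of 0.11 and 0.25 and a difference at percentile 17.7. Hmga2 was among those enriched in the wild type, whereas Myc and Hras were 2.78-fold and 2.08-fold lower. In the list of let-7 hosts and let-7 pathway genes, Huwe1, Dicer1 and Tut4 were enriched 3.58-fold, 2.42-fold and 2.05-fold in the mutant and none of 9 was enriched in the wild type, with medians of 0.08 and 0.25 and a difference at percentile 2.995. Splicing factors and RNA-binding proteins had medians of 0.32 in the wild type (percentile 100) and −0.27 in the mutant (percentile 98.97), the latter 0.32 after centring, and 34 of 48 carried a wild-type peak against 19 a mutant peak, with a difference at percentile 68.8. Taf15 and Hnrnpf were enriched 2.44-fold and 2.41-fold in the wild type, and in the mutant Sf3b1 was enriched 2.71-fold and Rbm25 was 2.48-fold lower. Translation factors had medians of 0.06 and −0.55, and 25 of 35 carried a wild-type peak against 10 a mutant peak, with a difference at percentile 71.2.

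Collagens, matrix glycoproteins, PI3K-mTOR and IGF signalling, JAK-STAT and NF-kB signalling and integrins had differences below the central 95% of random lists matched on level, integrins not once gene span was matched too. For 11 collagen genes the medians were −0.59 in the wild type and 0.37 in the mutant, with a difference at percentile 0.0700, although Col1a1 and others stood at low levels. For 19 matrix glycoprotein and proteoglycan genes the medians were −0.58 and −0.11, the latter 0.48 after centring, and the difference lay at percentile 0.0200. Of this list, Hspg2, which encodes perlecan, and Fbln2 were 2.41-fold and 2.38-fold lower in the wild-type IP. PI3K-mTOR and IGF signalling genes had medians of −0.14 and 0.35 (percentile 0), the former above 0 after centring. Against the list's direction, Igfbp7 was 2.60-fold lower in the wild type and 3.42-fold lower in the mutant. JAK-STAT and NF-kB genes had medians of −0.29 and −0.16 (percentile 0.130), the latter above 0 after centring. Integrin and adhesion genes had medians of 0.09 and 0.05, and their difference of 0.01 became −0.30 after centring; it lay at percentile 1.24, and at 29.1 once lists were also matched on gene span. Flna and Itga1, encoding filamin A and an integrin, were enriched 2.64-fold and 2.60-fold in the mutant, whereas Cd9 and Zyx were 3.51-fold and 2.69-fold lower there.

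For the other lists the difference lay within the central 95% of random lists matched on level. The medians in the wild type and the mutant were −0.53 and −0.27 for matrix remodelling enzymes and −0.40 and −0.48 for pan-fibroblast markers. They were −1.22 and −0.89 for myofibroblastic, −0.35 and −0.84 for inflammatory and −0.58 and −1.19 for antigen-presenting CAF markers. The myofibroblastic difference lay at percentile 3.96, and at 0.840 once gene span was matched too. For members in the upper 50% by level it lay at percentile 59.5. Medians were −0.26 and −0.05 for TGF-beta signalling, the latter 0.55 after centring, −0.05 and −0.44 for the cell cycle and −0.49 and −0.57 for glycolysis. They were −0.17 and −0.55 for endoplasmic reticulum chaperones and translocon genes, and −0.82 and −0.93 for epithelial markers. Tgfbr1 was enriched 2.44-fold in the wild type, and the translocon subunit gene Sec61b was 10.6-fold lower in the mutant. Lists with under 5 measured members received no percentile: medians were 0.18 and −1.67 for macrophage and leukocyte markers, −0.62 and −0.40 for endothelial markers, −1.06 and −0.65 for pericyte and smooth muscle markers, and the small RNA list held 2 measured genes, Terc and Rmrp, the latter with log2 ratios of 0.25 and −2.31.

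**Figure D4:**
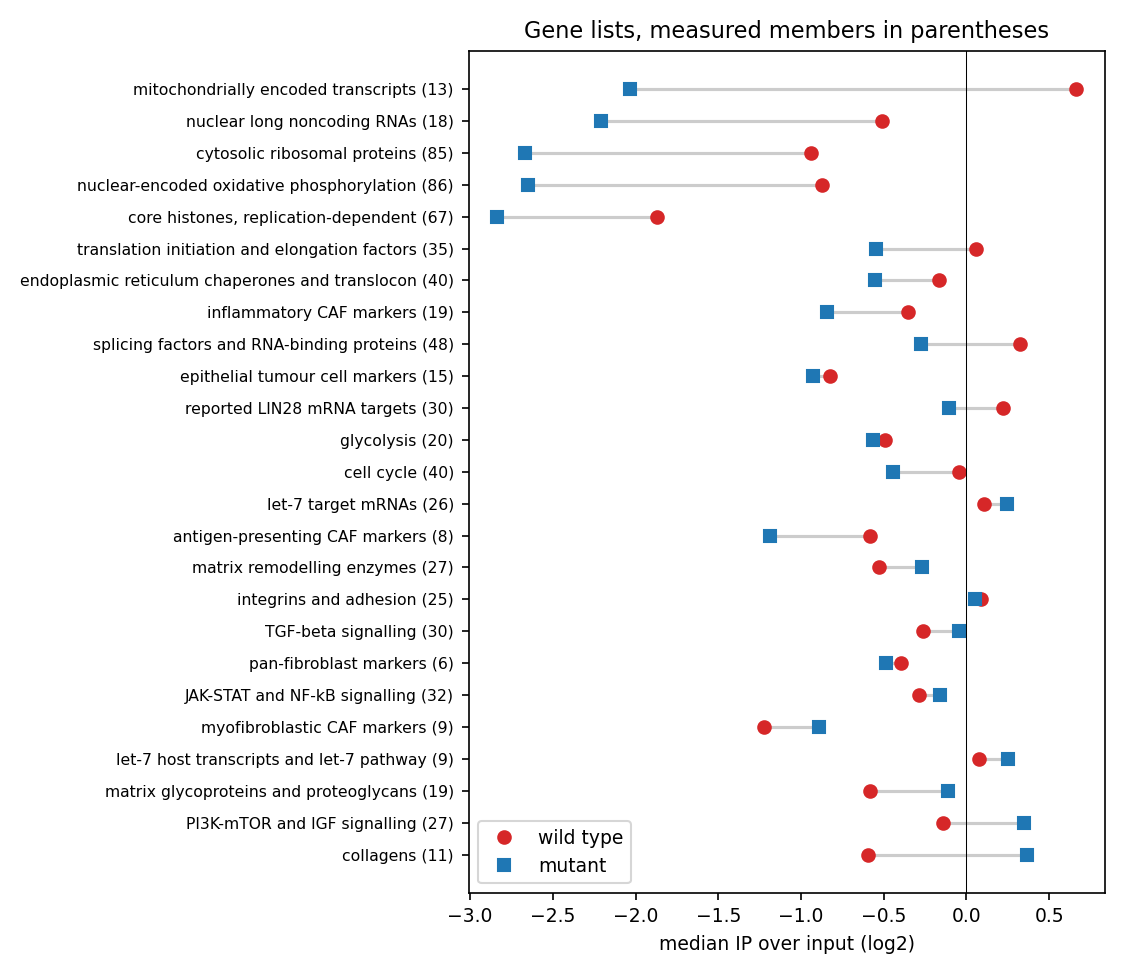
Median log2 ratio of IP over input for each list with at least 5 measured members (number in parentheses) in the wild type (circles) and the mutant (squares), 1 library on each side of each ratio. Mitochondrially encoded transcripts stand at 0.66 and −2.04, cytosolic ribosomal proteins at −0.94 and −2.67, and collagens at −0.59 and 0.37.

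The peaks showed where along the RNA recovery was concentrated. Of the wild-type peaks, 5911 (49.6%, 95% interval 48.7 to 50.5) overlapped a mutant peak, and of the mutant peaks, 5763 (36.2%, 35.4 to 36.9) overlapped a wild-type peak. With the mutant list shortened to the length of the wild-type list, the shares were 41.2% and 39.0%. The folds below are the authors' own. The strongest named peaks of the wild-type list without a mutant counterpart lay in Hpf1 (8:60899917-60900225, fold 48.6), which encodes a cofactor of PARP enzymes, in the innate sensor gene Sting1 (18:35740326-35740666, fold 42.5) and in Ap1s2 (X:163926712-163929361, fold 33.7). Others of this group lay in Ube2d3, Fmr1, Rpl22l1, Otud4, Naf1, Tmed5 and Dzip3, with folds from 22.6 to 29.3. Such a peak does not set the whole gene apart. Dzip3, Otud4, Fmr1 and Ube2d3 carried 10, 8, 2 and 1 mutant peaks elsewhere, whereas Hpf1, Sting1, Ap1s2, Rpl22l1, Naf1 and Tmed5 carried 0. Otud4 was enriched in both constructs, 3.84-fold in the wild type and 2.19-fold in the mutant. Hpf1 and Sting1 were enriched 4.63-fold and 2.67-fold at the gene level in the wild type and were 2.80-fold and 2.77-fold lower in the mutant. Shared peaks were ranked by their fold in the wild-type list. Apart from peaks assigned to Cmss1 and Filip1l, Hmga2 held the strongest named one there (10:120462675-120462907, fold 50.8). Sos1, Tasor, Tm9sf3, Vps54, Pik3c2a, Picalm and Ppip5k2 followed, with folds from 34.4 to 44.9. By the fold in the mutant list, the strongest named shared peak apart from Cmss1 and Filip1l lay in Vps13a (fold 43.1). Predicted genes aside, the strongest mutant peaks without a wild-type counterpart lay in Atm (9:53493058-53493458, fold 34.1), Macf1 (fold 28.4), Lyst (fold 26.8) and Vps13c (fold 21.5). Elsewhere these genes carried 17, 44, 8 and 4 wild-type peaks.

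The highest folds of both lists belonged to a few sites that were present in both. The strongest peak of each list lay at 17:39843313-39848713 in the wild type and 17:39845463-39848162 in the mutant, with folds of 2217 and 2169. It lay outside the genes of both tables, within another RefSeq gene span. Peaks of like fold in both lists do not set the wild type apart from the mutant. A site at 16:57391113 carried peaks on both strands in both lists, assigned to Cmss1 and Filip1l, and both genes had more RNA in the input than in the IP. The mitochondrial genome held 13 wild-type peaks and 0 mutant peaks.

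Peaks lay mostly within genes on the sense strand, 97.4% of them in the wild type (95% interval 97.1 to 97.7) and 96.2% in the mutant (95.9 to 96.5). Antisense peaks made up 1.16% and 2.30%. Of peaks in genes, 37.3% in the wild type (36.4 to 38.2) and 29.5% in the mutant (28.8 to 30.2) had their summit in the last 10% of the gene span. The share was 36.8% for wild-type peaks without a mutant counterpart and 24.9% for mutant peaks without a wild-type counterpart. The genes holding these peaks had median spans of 40.0 kb and 98.3 kb. Position was taken along the gene span, so the 2 shares compare genes of unlike span. Introns, exons and untranslated regions were not told apart.

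Among genes in both tables, 1735 carried peaks in both lists, 1617 in the wild-type list alone and 747 in the mutant list alone. Of 10842 genes with a level of at least 1 in an IP, 3338 carried a wild-type peak and 2474 a mutant peak; 1733 carried both, where 762 would be shared by independent lists. Genes with a peak in the wild type alone had median log2 ratios of 0.47 in the wild type and −0.43 in the mutant, and those with a peak in the mutant alone had −0.17 and 0.49. Their median spans were 25.8 kb and 55.5 kb. Of the 528 wild-type-specific genes, 286 carried a wild-type peak.

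Let-7 precursor loci, the classical substrates of Lin28 proteins, carried few peaks. Of 12 let-7 family loci in the RefSeq annotation of GRCm38, 2 overlapped a wild-type peak and 0 a mutant peak. These were Mirlet7d (13:48536012-48536114) and Mirlet7f-1 (13:48537829-48537917), both inside 1 wild-type peak at 13:48535497-48538161 with a fold of 9.16, which ended short of Mirlet7a-1. A wild-type peak with a fold of 9.21 also lay within 1 kb of Mirlet7i, and mutant peaks with a fold of up to 6.002 lay within 1 kb of Mir98. The search covered both strands, and the mutant peaks near Mir98 lay on both. Mir98 lies within the span of Huwe1, which carried 71 mutant peaks. Mature microRNAs are too short for this library type and were not measured. Levels of the let-7 precursors in the inputs were not examined, so the few peaks do not show how far precursors were bound.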

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

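The tests of explanations in this part, and the matching on gene span, were chosen after the results were seen. The genes were singled out because they passed the threshold in opposite directions in the constructs, IP over input, with 1 library on each side. The collagen and mitochondrial lists were singled out because their medians lay on opposite sides of 0, also after centring. In the wild type, 9 of 11 collagen genes and 11 of 13 mitochondrial genes were neither enriched nor lower. The difference was not tested. The ribosomal protein and oxidative phosphorylation lists, lower in both constructs, were chosen for the size of their difference.

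In 12 named genes without a 0, the gene was enriched in the wild-type IP and lower in the mutant IP. The wild-type log2 ratio exceeded the mutant ratio by 5.40 for Rpl22l1, 4.96 for mt-Co3, 4.66 for Nsmce1, 4.38 for Smim19, 4.19 for Mterf1a, 4.12 for Snrpe, 3.83 for Rpp38, 3.70 for Hpf1, 2.89 for Sting1, 2.22 for Snai2, 2.21 for Cav1 and 12.30 for H2ac18, the last set by the pseudocount, since the wild-type input lies below it, in a gene with near-identical copies that can share reads. Snai2 stood below a level of 1 in the wild type. In the mutant, Cav1, Snai2, Hpf1 and Sting1 were no longer lower at the threshold after centring, nor Snai2 and Smim19 with a pseudocount of 1. With a pseudocount of 5, Cav1, Mterf1a, Smim19, Sting1 and Snai2 were no longer lower in the mutant. Mterf1a, Rpp38, Sting1 and Snai2 were then no longer enriched in the wild type, Snai2 already with a pseudocount of 0.1. Mterf1a and Smim19 stood at 0.419 and 0.411 in the mutant IP. Over all genes in both tables, 152 were enriched in the wild type and lower in the mutant, and 23 showed the converse. The collagen list differed by −0.75, with a median below 0 in the wild type and above 0 in the mutant. In the mutant, 0 of its 11 genes were enriched and 0 lower. Once lists were also matched on gene span, its mutant median moved from percentile 99.7 to 88.4. Its difference then lay at percentile 1.045.

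Mitochondrially encoded transcripts differed by 2.70, the largest gap among the lists with a percentile. Once random lists were also matched on gene span, the list's mutant median moved from percentile 0.695 to 98.6. Against genes of like level and span the list was thus not low in the mutant. Its difference then lay at percentile 99.9. Unequal levels in the inputs do not account for the difference, since the median input ratio of the 13 genes was 0.0450 on the log2 scale, wild type over mutant. A trend with RNA length alone is argued against only as far as histone genes, whose transcripts have 1 short exon, stand for short RNAs. The lower quartile of the mitochondrial difference was 2.28, above the upper quartile of 1.48 in the histone genes. The histone list includes pseudogenes and near-identical copies that can share reads, which limits this comparison. Unequal recovery in single immunoprecipitations and a difference in binding by the wild-type and mutant proteins cannot be told apart with 1 library per group.

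Ribosomal protein and oxidative phosphorylation mRNAs were less depleted in the wild-type IP than in the mutant IP. Unequal inputs do not account for the ribosomal protein genes, whose median input ratio was 0.14 against a difference of 1.65. A trend with RNA length alone stays open: the upper quartile of the histone difference, 1.48, lay above the lower quartile of the ribosomal protein difference, 1.13, although the list kept percentile 100 when random lists were matched on gene span. Gene span is a poor stand-in for the length of the mature RNA. No biological explanation was tested for these lists.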

How the results depend on the processing

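The pseudocount of 1, the pseudocounts for the difference, and the settings on inputs, gene classes and gene span were chosen after seeing the data. Depth is unknown, so low levels have no counting error; the cause of the changes below was not tested except where a stricter rule by construction leaves fewer features.

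The share of wild-type peaks shared with the mutant was 37.1% at a reciprocal overlap of 50%, 48.5% for q-values at or under 1e-05, 38.7% for folds at or above the pooled median and 41.2% with the mutant list shortened to the length of the wild-type list; for mutant peaks it was 27.7%, 35.1%, 24.8% and 39.0%. At 50% of the shorter peak both shares stayed within their intervals. Mutant peaks in sense genes made up 96.7% at the stricter q-value. The shortened list left 401 genes with a mutant peak alone.

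Enriched and lower genes in the wild type numbered 318 and 931 at a fold of at least 4, 480 and 1209 in the upper 50% by level, 509 and 1501 with a pseudocount of 1, and 251 and 669 with 5; centring gave 1804 enriched genes. In the mutant they numbered 219 and 2344, 447 and 2213, 440 and 3082, and 232 and 1700, and 2298 and 3294 after centring. Wild-type-specific and mutant-specific genes numbered 160 and 60 at a fold of at least 4, 191 and 112 in the upper 50% by level, 244 and 119 with a pseudocount of 1, 118 and 63 with 5, and 310 and 152 with inputs within 2-fold. After centring they numbered 583 and 754, which turns the balance of 528 and 272, and after centring within span classes 597 and 461. A pseudocount of 0.1 kept all these counts within 1.5-fold, and protein-coding genes alone and genes with no 0 did so for the wild-type-specific and mutant-specific counts, for which they were run.

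Of 25 lists, 10 lay outside the central 95% of the difference, against 10 unmatched, 8 in the upper 50% by level and 9 matched on span. Unmatched, integrins came inside at 9.36 and endoplasmic reticulum genes went outside at 98.07. In the upper 50% by level, histones came inside at 96.97, and collagens and pan-fibroblast markers had too few members for a percentile. With span, the histone list moved to percentile 3.07, integrins to 29.1 and myofibroblastic CAF markers, within the central 95% before, to 0.840. In the upper 50% by level the myofibroblastic list stood at 59.5. Centring turned the sign of 5 called medians: in the mutant to 0.49 for reported LIN28 targets, 0.32 for splicing factors, 0.48 for matrix glycoproteins and 0.55 for TGF-beta signalling, and in the difference to −0.30 for integrins. Of 1240 values of named genes under 4 alternatives, 141 fell below the threshold and 17 passed it. Of the values past the threshold as deposited, 0 changed sign. Sign changes of values short of the threshold, which centring can bring about, were not counted. Exonic peaks, motifs and a deposited peak annotation were not run, since exon models, a genome and such an annotation were not used here. No paired analysis was possible because each group held 1 library.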

Other observations

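In this part, the tests on cell markers were chosen after the values were seen, and the test on the inputs of wild-type-specific genes was set before its result. Many genes known to respond to interferon stood higher in the mutant input. Of a list of 50, written after the inputs had been compared and so no independent test, 45 were measured, of which 43 were at least 2-fold higher in the mutant input and 0 in the wild-type input on the scale of level + 1, with a median of 14.3-fold. Isg15 stood at 163 FPKM in the mutant input and 4.63 in the wild-type input, Ifit3 at 86.6 and 3.44 and Usp18 at 56.8 and 1.21. Ly6e, also known to respond to interferon but not on that list, went the other way, at 0.174 in the mutant input and 114 in the wild-type input. The antigen presentation genes B2m and H2-D1 stood at 748 and 310 in the mutant input and at 188 and 78.8 in the wild-type input. The chemokine gene Cxcl1 and the iron-binding protein gene Lcn2 stood at 104 and 100.4 in the mutant input and at 2.76 and 3.90 in the wild-type input.

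Among genes that stood higher in the wild-type input, also picked after their values were seen, Lgals4 stood at 333 in the wild-type input and 34.7 in the mutant input, the claudin gene Cldn18 at 41.1 and 0.226, the protease gene Tmprss2 at 39.9 and 0.272 and Anxa13 at 195 and 4.82. The actin-bundling gene Fscn1 stood at 53.1 and 0.342.

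The marker levels raise the question of which cells were in the cultures labelled as CAFs. A small share of epithelial cells among fibroblasts is argued against, since Krt8 stood 833-fold above Col1a1 in the wild-type input and 1221-fold in the mutant input, where a majority of collagen-producing fibroblasts would place Col1a1 high. Cultures made mainly of epithelial cells are a candidate explanation: 9 of the 15 measured epithelial markers stood at 10 FPKM or above in both inputs, 2 of the list's 24 genes being also on the antigen-presenting CAF list. These 9 were Cdh1, Elf3, Esrp2, Krt8, Krt18, Krt19, Krt20, Lgals4 and Ocln. That explanation remains open, since 4 of 6 measured fibroblast markers, Vim, Fn1, S100a4 and Sparc, also stood at 10 or above. Only these 6 of the 20 fibroblast markers were listed in both tables, and Col1a1 and Pdgfra among them stood at 1.33 or below. Fibroblasts that gained keratins cannot be told apart from epithelial cells that gained Vim. The difference between the inputs may also reach the comparison of the constructs: 37.9% of wild-type-specific genes had a mutant input at least 2-fold above the wild-type input, against 8.70% of all genes, with a pseudocount of 0.01, while 310 of the 528 had inputs within 2-fold. At a given mutant IP level a high mutant input raises the difference, so the call can favour such genes and part of the excess may be built in. Where the mutant IP follows its input, the difference need not rise. The 45 measured interferon genes had a median difference of 0.27, against 0.32 over all genes in both tables. How many calls rest on the inputs stays open.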
